A study of Homo sapiens with 20 samples.

How the data were processed

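Small RNA was sequenced from 2 kinds of sample of patients with metastatic castration-resistant prostate cancer: exosomal RNA from plasma (10 libraries) and RNA from the exosomal region of dried blood spots (10 libraries). Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the QIAseq miRNA kit, which adds a molecular identifier to each cDNA. Each library has a deposited table of whole-number read counts per mature miRNA, made by the authors. FastQC and fastp are named in the submitters' processing notes. The aligner, the miRNA annotation and its version are not given in the sources used here, nor is it stated whether reads sharing a molecular identifier were collapsed.

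Every table lists 2888 rows under 2656 mature miRNA names, of which 168 names stand on more than 1 row, 1 per genomic precursor. Between 85.1% and 92.3% of these repeated names, depending on the library, held equal counts on all their rows. Names with 0 reads on every row count as equal in this share. Summed over the repeated names, the smallest rows held at least 99.6% of the reads of the largest in every library. Each repeated name was therefore kept once, with its largest count, and the sum over rows was tried as an alternative. At least 1 read in any library was found for 1199 names. Kept once, the plasma libraries held 7784102 to 42278937 reads and the dried blood spot libraries 7944430 to 43200701. A count of 3 reads corresponds to between 0.0755 and 0.386 CPM, depending on the library. Such floors cover counting error only, because reads amplified from 1 molecule would not be independent.

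Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group with a minimum count of 10, trimmed mean of M-values (TMM) scaling, robust quasi-likelihood F-tests, and Benjamini-Hochberg adjustment with a threshold of 0.05. All 20 libraries entered the fit, with no covariate. The standard error of a log2 fold change was taken as its size divided by the square root of F. A second test (glmTreat) asked for a change of more than 2-fold. Printed CPM values are relative to the TMM-scaled library size unless said otherwise, so that their sum differs between libraries, and correlations and distances used log2 CPM with a prior count of 2. Lists of miRNAs were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with the correlation estimated per list, and with fry, for lists with at least 3 tested members. Differences of single measures between the kinds were tested with two-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest p they can give. These used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

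The tests, the 15 miRNA lists and the rule for named miRNAs were fixed before the data were examined. The rule took 13 fixed miRNAs, the 6 most abundant of each kind, and the 8 largest rises and 8 largest falls among miRNAs with adjusted p under 0.05 and a mean of at least 100 CPM. From each list it took the 2 tested members with the smallest adjusted p and the 2 most abundant, which gave 54 miRNAs in all. For the correlation over equal sample numbers it took the 6 with the smallest adjusted p. Other miRNAs are named below as members of a list, and were chosen after their values were seen. The lists cover erythroid, platelet, myeloid, lymphoid, liver, striated muscle, epithelial, stromal and endothelial, and brain miRNAs. They also cover the let-7 family, the miR-17-92 cluster with its paralogs, the imprinted DLK1-DIO3 cluster, circulating miRNAs from the prostate cancer literature, entries known to overlap other RNAs, and a placental cluster as background.

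Precursors were placed by name in GENCODE release 29 (GRCh38), 1-based, since the tables hold no coordinates. GC content was read from 22 bases of the named hairpin arm beside the loop, as a stand-in for the mature sequence, which was not used here. This window replaced the whole arm before any GC result was seen. For names that give no arm, such as miR-451a, GC content was read from the whole hairpin instead. A GC value was available for 98.1% of the tested miRNAs.

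On counts simulated from these libraries over 368 miRNAs, the comparison of dried blood with plasma recovered 23.9% of miRNAs changed 2-fold, 64.2% of those changed 4-fold and 87.9% of those changed 16-fold. It called 1.19% of the unchanged miRNAs. A simulated 4-fold rise of the erythroid list was found, with 1 other list called, which shares members with it. The miRNAs were simulated independently of each other, so this does not show how the list test behaves when members vary together. For the correlation of single miRNAs between the kinds, 96.7% of 30 pairs simulated with an r of 0.98 among 78 miRNAs were recovered, with 1 other call. Weaker correlations were not simulated, so this does not show whether the test would find them.

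Alternatives fixed in advance were DESeq2 size factors, library totals alone, no filter or a filter of 10 CPM in 10 libraries, the sample number as a block, repeated names summed, each number left out, DESeq2 1.42.0 and limma voom. Fits without plasma libraries 9 and 10, without dried blood libraries 5 and 7, with a GC correction, and on counts divided by each library's commonest low count were added after seeing the data. Survival and other clinical data were not analysed here. No 2 libraries of a kind held the same counts: the closest pair, dried blood 1 and 3, had a chi-square of 308.5 per degree of freedom. This chi-square takes reads as independent and grows with depth. It therefore cannot tell whether 2 libraries came from the same RNA or donor.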

Results

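MicroRNAs were profiled in plasma exosomal RNA and in RNA from the exosomal region of dried blood spots, with 10 libraries of each kind from patients with metastatic castration-resistant prostate cancer. Exosomes are small vesicles released by cells, and a dried blood spot is whole blood from a finger prick dried on a carrier. The series title concerns miRNA markers from fingerstick blood, so the comparison asks how the miRNA content of dried blood differs from that of plasma. The labels describe the sets as matching without stating which patient gave which library. The p-values therefore measure the spread between these libraries.

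Libraries held 7784102 to 42278937 miRNA reads in plasma and 7944430 to 43200701 in dried blood. The mean log10 total was 7.15 ± 0.251 in plasma and 7.35 ± 0.259 in dried blood (SD, n = 10 each), a difference of 0.197 within the spread between libraries (permutation test, two-sided p = 0.101). In 19 of the 20 libraries, rare miRNAs clustered around one read count of 12 or more in place of piling up at 1 read. This commonest count ranged from 40.9 to 198.8 reads in plasma and from 5.6 to 111 in dried blood.

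**Figure D1:**
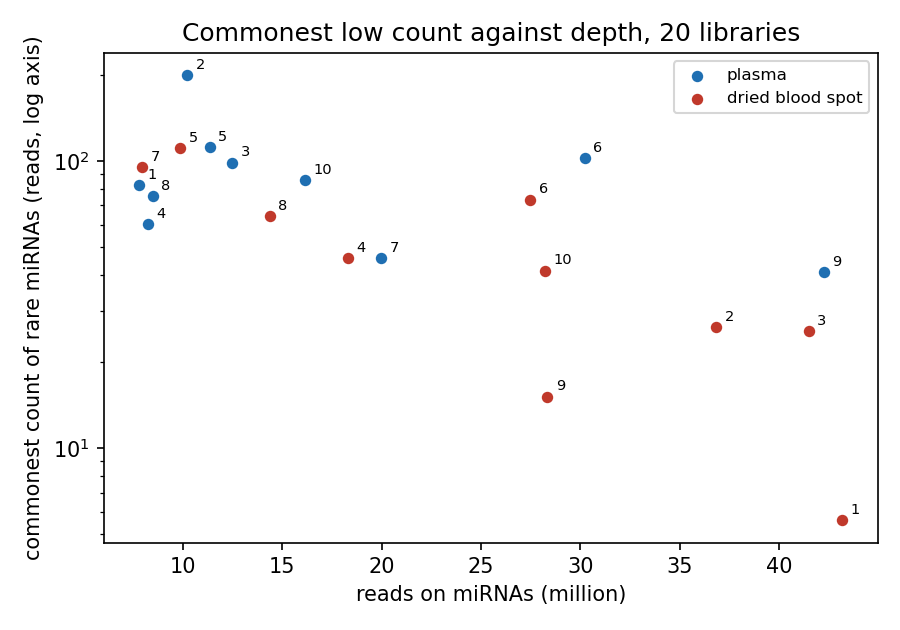
Commonest count among miRNAs with more than 2 reads (vertical, reads, log axis) against reads on miRNAs (horizontal), 1 point per library, numbered by replicate. The plasma libraries lie between 40.9 and 198.8 reads and the dried blood libraries between 5.6 and 111.

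miR-16-5p, a miRNA abundant in red cells, led both kinds, with 28.9 ± 12.2% of plasma reads and 42.9 ± 2.35% of dried blood reads (SD, n = 10). In plasma it was followed by miR-486-5p (9.23 ± 4.93%), the endothelial and platelet miRNA miR-126-3p (8.69 ± 5.88%) and let-7a-5p (5.08 ± 2.28%). In dried blood it was followed by let-7a-5p (9.79 ± 1.16%), let-7f-5p (5.52 ± 0.834%) and let-7g-5p (4.73 ± 0.451%). miR-122-5p, the main hepatocyte miRNA, took 3.91 ± 5.34% of plasma reads and 0.00121 ± 0.00107% of dried blood reads. The 10 most abundant miRNAs held 74.6 ± 6.00% of plasma and 81.9 ± 1.38% of dried blood reads (permutation p = 0.00244, two-sided). Plasma libraries 9 and 10 stood apart from the other 8, with miR-16-5p at 500904 and 481233 CPM before TMM scaling against a mean of 238130 in those.

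At least 10 reads were found for 429.7 ± 87.1 miRNAs per plasma library and 431.3 ± 132.4 per dried blood library (permutation p = 0.976, two-sided). With every library thinned to the smallest total the order turned, with 410.4 ± 66.4 in plasma and 338.9 ± 52.0 in dried blood (permutation p = 0.0133). In at least 5 of 10 libraries, 307 miRNAs were detected in both kinds, 100 in plasma alone and 109 in dried blood alone. After thinning these numbers were 271, 117 and 59. Thinning can bring rare miRNAs under 10 reads where they cluster at a low count in a deep library. This count was 5.6, 26.3, 25.5 and 15.1 reads in dried blood 1, 2, 3 and 9, and 40.9 or more in plasma. The turn after thinning therefore does not by itself show fewer miRNAs in dried blood. Across 368 miRNAs, which are not independent replicates, the mean log2 CPM of the kinds correlated with a Spearman rho of 0.65 and a Pearson r of 0.75. The median rho between single libraries was 0.87 within plasma, 0.89 within dried blood and 0.63 between the kinds. Libraries lay 2.06 ± 0.37 log2 units from the mean of the others in plasma and 1.85 ± 0.60 in dried blood (permutation p = 0.347, two-sided). The distances within a kind depend on each other through these means, so this p is approximate.

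Dried blood held far more of the erythroid miRNAs miR-451a and miR-144-3p, and more of 13 of 15 members of the miR-17-92 family. Plasma held far more of miR-122-5p, miR-483-5p and 10 of 11 tested members of the DLK1-DIO3 cluster. miR-451a was 30.1-fold higher in dried blood, at 22255 ± 14843 CPM against 740.3 ± 299.9 (SD, n = 10; log2 fold change 4.91, SE 0.37, edgeR adjusted p = 4.83e-11). miR-122-5p was 1656-fold lower, at 15.1 ± 13.4 CPM against 24993 ± 28199 (log2 fold change -10.69, SE 0.95, adjusted p = 1.1e-08). All 10 dried blood libraries lay above the plasma median for miR-451a and below it for miR-122-5p. Among 368 tested miRNAs, 81 rose and 97 fell in dried blood (edgeR quasi-likelihood test, Benjamini-Hochberg), and 190 were not called. Changes of more than 2-fold were called for 135, of which 55 rose and 80 fell.

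The split between rises and falls depended on the scaling and on the method. With library totals alone 49 miRNAs rose, so that rises made up 25.4% of calls in place of 45.5%, and 6 of the 178 called miRNAs changed sign. The median log2 fold change of all tested miRNAs was -0.24 with TMM, -0.31 with DESeq2 size factors and -1.09 with totals alone. TMM factors averaged 1.40 in plasma and 0.754 in dried blood. limma voom called 108 rises and 105 falls, and a GC correction 96 rises and 84 falls. The GC correction also re-centred the mean log2 level of each library, and the median log2 fold change with it was 0.089. Values and lost or gained calls under the GC correction, here and below, therefore mix a change of scaling with GC. Without plasma libraries 9 and 10, 82 rose and 111 fell. On counts divided by each library's commonest low count, 136 miRNAs could be tested, of which 50 rose and 58 fell. Of 102 calls that could be tested there, 101 were kept, and 0 changed sign.

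**Figure D2:**
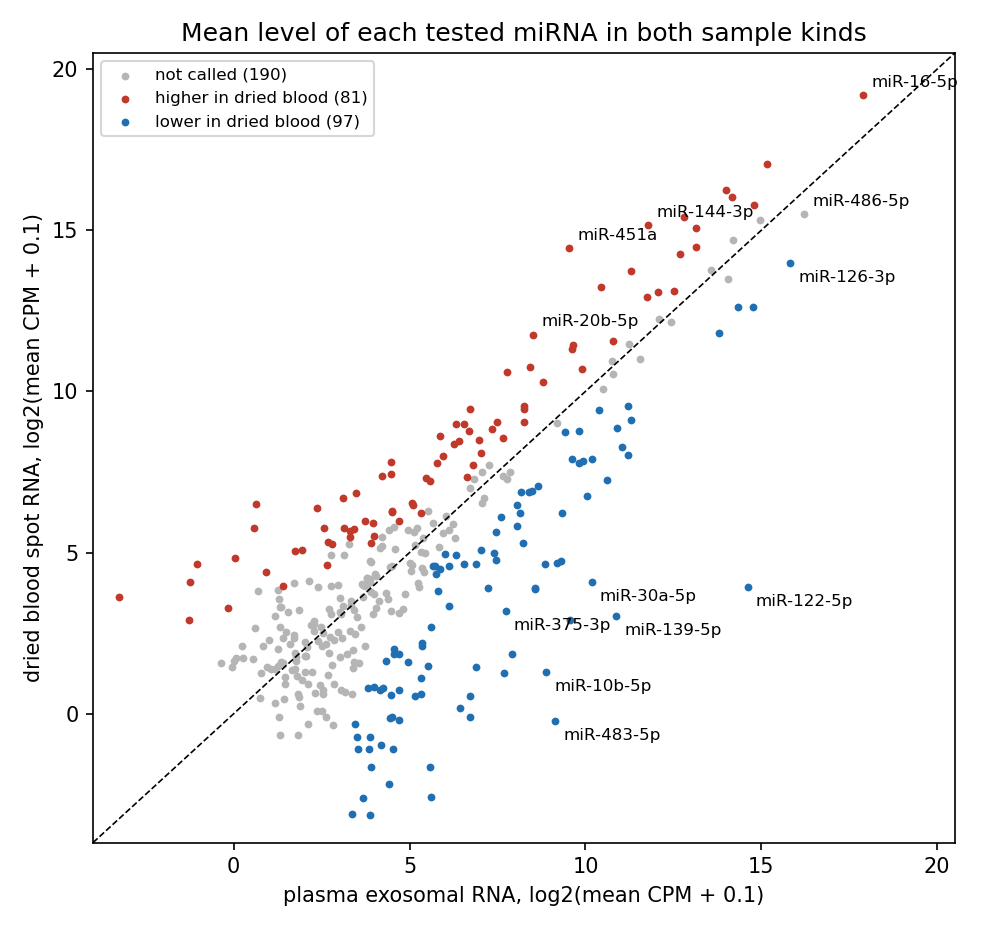
Mean level of each of 368 tested miRNAs in plasma (horizontal) and dried blood (vertical), as log2 of the mean CPM with a small constant added, coloured by the edgeR call at an adjusted p of 0.05. The dashed line marks equal levels; 81 miRNAs were called higher and 97 lower in dried blood, with miR-451a far above and miR-122-5p far below the line.

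Of 17 erythroid miRNAs, 13 rose, 1 fell and 3 were not called in dried blood (adjusted over the list alone, 13 rose and 2 fell). miR-451a and miR-144-3p are made from neighbouring hairpins on chromosome 17 (GRCh38, 28861369 to 28861440 and 28861533 to 28861618, minus strand), both inside an exon of the lincRNA AC024267.1. miR-144-3p rose by 3.37 on the log2 scale (SE 0.20, adjusted p = 6.96e-13) and miR-16-5p by 1.30 (SE 0.31, adjusted p = 0.00106). miR-16-5p comes from hairpins in introns of DLEU2 on chromosome 13 (50048973 to 50049061) and of SMC4 on chromosome 3 (160404745 to 160404825). miR-486-5p, encoded in an intron of the red cell ankyrin gene ANK1 on chromosome 8 (41660441 to 41660508), was not called (log2 fold change -0.72, SE 0.34, adjusted p = 0.0846). It was called lower under 7 alternatives, among them DESeq2 size factors (-0.74, adjusted p = 0.0454) and totals alone (-1.44, adjusted p = 6.52e-05), and stood below the plasma median in 10 of 10 dried blood libraries. With the GC correction, which also re-centres each library, miR-486-5p stood at -0.038. Of the erythroid list, 2 fell with DESeq2 size factors and 3 with totals alone. The ratio of miR-451a to miR-486-5p, which scaling does not touch, had a log2 mean of -1.30 ± 0.75 in dried blood and -6.41 ± 1.06 in plasma, with no overlap between libraries. The log2 ratio of miR-451a to miR-23a-3p, used as an index of red cell content, was 8.26 ± 0.78 against 1.89 ± 0.84 (two-sided permutation p = 1e-05, the smallest they can give). This difference of 6.37 was larger than that of 2 other ratios. It was 3.15 for miR-16-5p to miR-23a-3p and 2.91 for miR-451a to let-7g-5p.

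**Figure D3:**
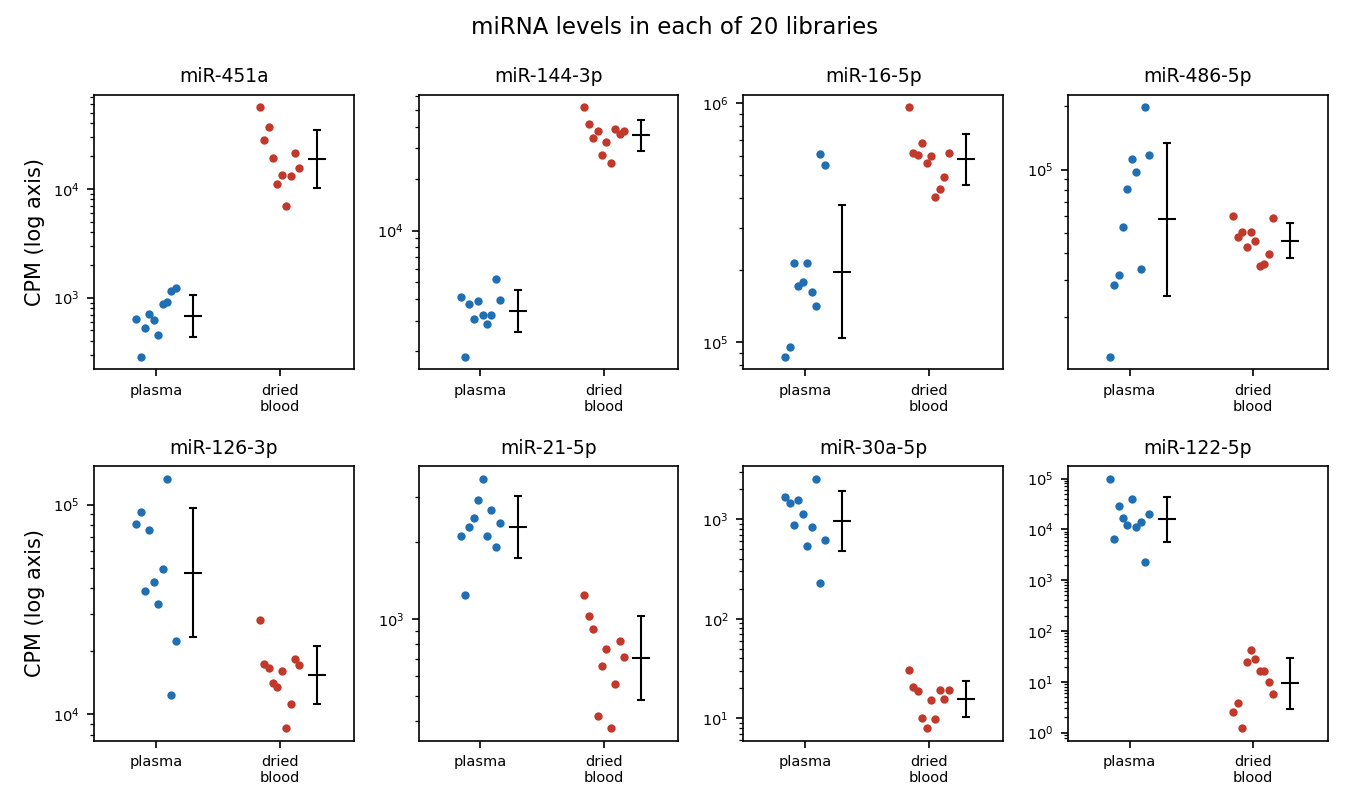
CPM of 8 miRNAs (log axis) in each of 10 plasma and 10 dried blood libraries; points are libraries, and the bar gives the mean ± 1 SD of log10 CPM. miR-451a and miR-144-3p are higher in every dried blood library than in any plasma library, miR-30a-5p and miR-122-5p are lower in every one, and miR-486-5p overlaps.

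The miR-17-92 cluster and its paralogs, which lie on chromosomes 13, X and 7, rose in 13 of 15 members, fell in 0, and 2 were not called (15 rose when adjusted over the list alone). miR-20b-5p rose by 3.26 (SE 0.26, adjusted p = 1.41e-10), miR-20a-5p by 2.78, miR-17-5p by 2.76 and miR-106b-5p by 2.75 on the log2 scale. With DESeq2 size factors and with library totals alone the number that rose was again 13. Of the let-7 family, 7 of 9 members rose, let-7e-5p fell by 2.07 and let-7i-5p was not called (log2 fold change 0.36, adjusted p = 0.281). let-7f-5p rose by 2.26 and let-7a-5p by 1.91. With totals alone 5 rose and 2 fell, let-7b-5p lost its call (0.11, adjusted p = 0.510) and let-7i-5p turned to -0.46 (adjusted p = 0.0164). It was called higher without plasma libraries 9 and 10 (0.63, adjusted p = 0.0119) and with the GC correction (0.98). Members of these families differ by few bases, so reads assigned between them are uncertain.

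White cell and platelet miRNAs were lower in dried blood in most called cases. With totals alone 13 platelet, 8 myeloid and 9 lymphoid miRNAs fell, and 1, 0 and 1 rose. Of 15 platelet miRNAs, 8 fell, 1 rose and 6 were not called: miR-126-3p fell by 1.85 (SE 0.32, adjusted p = 2.39e-05) and miR-24-3p by 2.04, whereas miR-191-5p rose by 2.43. Of 10 myeloid miRNAs, 6 fell, 2 rose and 2 were not called. miR-223-3p, a granulocyte miRNA, fell by 1.73 (SE 0.54, adjusted p = 0.0102), miR-21-5p by 1.66 and miR-27a-3p by 2.22, and miR-23a-3p fell too (adjusted p = 0.000132). miR-142-5p rose by 1.01 (adjusted p = 0.000109) and miR-142-3p by 0.77 (adjusted p = 0.0298). The miR-142-3p call was lost under 13 alternatives, among them 6 of 10 fits leaving out a number, DESeq2 (0.61, adjusted p = 0.0662) and the GC correction (0.47, adjusted p = 0.164). With totals alone it stood at -0.30 (adjusted p = 0.464) and miR-142-5p lost its call (0.13, adjusted p = 0.450), as it did with the GC correction (0.41, adjusted p = 0.182). Of 12 lymphoid miRNAs, 7 fell, 1 rose and 4 were not called, with miR-150-5p falling by 1.90, miR-29a-3p by 3.17 and miR-181b-5p by 2.41. miR-150-5p lost its call with the GC correction (-1.07, adjusted p = 0.132). miR-29c-3p was not called (-0.25, adjusted p = 0.455), but was with totals alone (-1.11, adjusted p = 0.000453).

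Called members of the solid tissue lists fell, with 1 exception, miR-194-5p (adjusted p = 0.0499). Many listed members did not pass the filter, and the counts below cover the tested ones. Tested were 5 of 12 liver, 8 of 12 stromal and endothelial, 4 of 9 striated muscle, 3 of 12 brain and 5 of 11 epithelial miRNAs. Of 5 liver miRNAs, miR-122-5p and miR-483-5p fell, miR-194-5p rose and 2 were not called. miR-122-5p is made from an exon of MIR122HG on chromosome 18 (58451074 to 58451158, plus strand). miR-483-5p, encoded in an intron of IGF2, averaged 565.9 ± 330.1 CPM in plasma and 0.754 ± 1.62 in dried blood, where 5 libraries had 0 reads. Of 8 stromal and endothelial miRNAs, 5 fell, 0 rose and 3 were not called: miR-10b-5p fell by 7.63 (SE 1.17), miR-10a-5p by 6.65 (SE 0.83) and miR-143-3p by 3.29 (SE 0.53). Of 4 striated muscle miRNAs, 3 fell, among them miR-206 (fell by 4.04, SE 1.26, call lost with the GC correction at -2.50, adjusted p = 0.107) and miR-378a-3p (fell by 1.58, SE 0.21), and miR-1-3p was not called (-0.48) except by limma voom (-1.66, adjusted p = 0.0160). Of 3 brain miRNAs, miR-9-3p fell by 5.41, while miR-128-3p (0.28) and miR-138-5p (-2.01) were not called, and miR-128-3p turned to -0.66 with totals alone (adjusted p = 0.0413) and to 1.20 with the GC correction (adjusted p = 0.00182). Of 42 listed members of the imprinted DLK1-DIO3 cluster on chromosome 14, 11 were tested, of which 10 fell and 1 was not called. miR-382-5p fell by 6.23 (SE 1.29), miR-376a-3p by 4.26 (SE 1.04) and miR-337-5p by 7.35 (SE 1.27). These 3 had 0 reads in 6, 4 and 7 dried blood libraries. Members with so few dried blood reads pass the filter mainly through plasma, which favours a fall. Of the other miRNAs with the largest falls, miR-139-5p fell by 7.87, miR-99b-5p by 6.47, miR-30a-5p by 6.10 and miR-30a-3p by 6.08. Leaving out 1 sample number, which removes 1 library of each kind, moved the size of several of these falls, all still called. Such fits brought miR-206 to -6.00, miR-382-5p to -7.56, miR-337-5p to -8.34 and miR-483-5p to -10.90. Others brought miR-9-3p to -6.84, miR-10b-5p to -8.48, miR-99b-5p to -7.22 and miR-122-5p to -9.99.

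Of 24 tested miRNAs from the prostate cancer literature, 11 fell, 8 rose and 5 were not called. miR-375-3p, an epithelial and neuroendocrine miRNA encoded on chromosome 2 (219001645 to 219001708, minus strand, with no annotated host gene), fell by 4.56 (SE 1.08, adjusted p = 0.00149). It averaged 211.9 ± 114.3 CPM in plasma and 9.04 in dried blood, where libraries ranged from 0 to 66.8 CPM. The highest value was in library 5, and without the libraries numbered 5 the log2 fold change of hsa-miR-375-3p was -6.35 (still called). miR-141-3p fell by 1.43 (SE 0.53, adjusted p = 0.0250), but it was not called without the libraries numbered 1 (-0.74, adjusted p = 0.240) or 4 (-1.35, adjusted p = 0.0613). DESeq2 (-0.68, adjusted p = 0.175), the block on sample number (-1.23, adjusted p = 0.123) and the GC correction (-0.36, adjusted p = 0.684) did not call it either. miR-182-5p rose by 2.85 (SE 0.26), and miR-107 was not called (-0.55, adjusted p = 0.0909), though it was called lower under 8 alternatives. Of 5 epithelial miRNAs, miR-375-3p and miR-141-3p fell, and miR-205-5p showed no difference that could be told from 0 (0.09, SE 0.74). miR-374a-5p, encoded in an intron of FTX on the X chromosome, rose by 3.34 (SE 0.38).

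Entries known to overlap other RNAs went both ways: 6 of 17 rose, 3 fell and 8 were not called. miR-1246 fell by 4.57 (SE 0.91) and miR-1290 by 4.50 (SE 0.91), and without the libraries numbered 7, where plasma held the highest values, hsa-miR-1246 stood at -3.72 and hsa-miR-1290 at -3.44 (both still called). miR-4454, an entry that overlaps tRNA sequence, rose from few reads: it had 0 reads in 9 of 10 plasma libraries and in 1 dried blood library. miRNAs of the placental cluster on chromosome 19, kept as background, had too few reads for any of 25 to pass the filter. They gave 210 to 900 reads in each of the 10 plasma libraries, and reads in 2 of 10 dried blood libraries, 77 at most.

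With a preset correlation of 0.01, camera called 7 of 14 tested lists: the miR-17-92 family (adjusted p = 1.2e-07), erythroid (3.37e-05) and let-7 (0.00472) lists were higher, and the DLK1-DIO3 (0.000791), stromal and endothelial (0.0147), platelet (0.0364) and striated muscle (0.0364) lists were lower. With the correlation estimated per list, none of the 14 was called: the adjusted p was 0.281 for the miR-17-92 family and for striated muscle, 0.334 for the erythroid and DLK1-DIO3 lists, 0.360 for the let-7 and stromal lists, and 0.483 for platelets. The estimated correlation ranged from 0.072 (striated muscle) to 0.52 (let-7), above the preset 0.01 for every list. With the estimated correlation, camera called the miR-17-92 list under DESeq2 size factors (adjusted p = 0.0270) and library totals alone (adjusted p = 0.00979). It also called the striated muscle list with no filter (adjusted p = 0.0210). The test by fry, which compares each list with no change and not with the other miRNAs, called 13 of 14 lists, all but the prostate literature list (adjusted p = 0.284). The preset-correlation adjusted p was 0.0947 for the myeloid and fragment lists, 0.0833 for lymphoid, 0.404 for liver and epithelial, 0.515 for brain and 0.537 for the prostate literature list. Without the libraries numbered 1 the platelet and striated muscle lists lost their calls (adjusted p = 0.0548 for both), and without those numbered 7 the platelet list did (0.0536). The stricter filter ended the platelet, striated muscle and stromal calls (adjusted p = 0.0739 each), the block on sample number the striated muscle call (0.0881), and the GC correction the platelet call (0.0557). On divided counts the platelet (0.291) and stromal (0.0869) lists were not called. The gains that follow were at the preset correlation, and none held with the correlation estimated per list. The lymphoid list gained a call without the libraries numbered 10 (0.0490), without plasma libraries 9 and 10 (0.0392), with totals alone (0.0419) and with no filter (0.0128). The myeloid list gained one with totals alone (0.0454), with no filter (0.0181) and with the GC correction (0.0184). The fragment list gained one with totals alone (0.0419) and with no filter (0.0119), and the epithelial (0.0192) and liver (0.0499) lists with no filter. Of the erythroid list, 7 members also stand on another list, as do 4 of the platelet list and 17 of the prostate literature list. So do 7 of the miR-17-92, 3 of the DLK1-DIO3 and 4 of the epithelial list. miR-20b-5p, miR-25-3p, miR-92a-3p and miR-363-3p, which rose, stand on both the erythroid and miR-17-92 lists. miR-382-5p, miR-409-3p and miR-376c-3p, which fell, stand on both the platelet and DLK1-DIO3 lists. The calls of these lists are therefore not separate results.

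**Figure D4:**
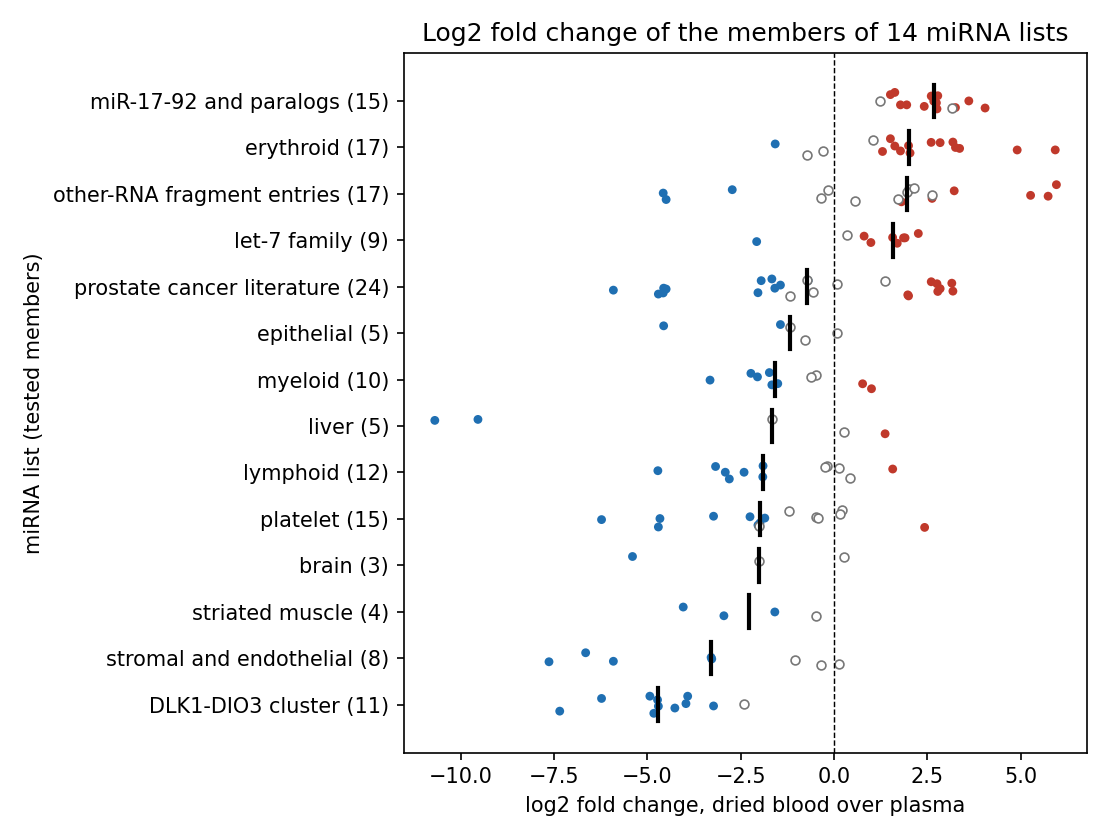
Log2 fold change (dried blood over plasma) of the tested members of 14 miRNA lists, with the number tested in brackets; filled points passed an adjusted p of 0.05, open points did not, and the bar marks the list's median. The miR-17-92 list has the highest median (2.67) and the DLK1-DIO3 list the lowest (-4.70).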

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

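The tests about plasma libraries 9 and 10 and about the clustering of low counts were chosen after the pattern and the values were seen, and the 2 tests on miR-451a against miR-486-5p before their result was. In 118 groups of 10 values checked, 5 held a library far from the others, where chance alone gives about 1 in 20. miR-1246 and miR-1290 stood at 3958 and 3663 CPM in plasma 7, against at most 471 and 419.5 in the other plasma libraries. miR-9-3p had 0 reads in plasma 10, where 3 reads would be 0.212 CPM, against 5.87 to 43.4 CPM in the other plasma libraries. let-7g-5p stood at 116283 CPM in dried blood 1 against at most 73335 in the others. miR-337-5p stood at 0.458 CPM in dried blood 3 against at most 0.105 in the others, a difference of few reads.

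Within the erythroid list miR-451a rose far more than miR-486-5p, which was not called, or was called lower under 7 alternatives. Scaling between libraries would leave their ratio alike in both kinds, but the lowest dried blood library lay 2.00 log2 units above the highest plasma library. The GC content used was 41.7% for miR-451a, from its whole hairpin, and 68.2% for miR-486-5p, from 22 bases of its arm. These are unlike measures, so the 2 values cannot be compared directly. Over the tested miRNAs log2 fold change barely followed GC (Spearman rho -0.11). After a GC correction miR-486-5p stood at a log2 fold change of -0.038, in place of -0.72. The correction also re-centres each library, which moves single values but not the difference between 2 miRNAs. The 2 miRNAs still differed by 5.02 log2 units (SE 0.44), against 5.63 (SE 0.50) before. Since the correction used the 2 unlike GC values, it cannot show how much of their difference goes with GC. Sample kind goes together with collection, drying and extraction, so a difference in the RNA of the samples and a difference in how it was recovered both stay open.

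Plasma libraries 9 and 10 lay nearest to the dried blood libraries on the first principal component, at -13.8 and -21.5 against -25.5 or lower for the others. Their miR-144-3p (4297 and 3478 CPM before TMM scaling) and miR-451a (936.5 and 1076) stood no higher than the highest of the other plasma libraries (7651 and 1188). Their log2 ratio of miR-451a to miR-23a-3p, the index of red cell content, went the other way. It was 3.22 and 3.40, against 0.95 to 2.03 in the other plasma libraries. With dried blood as the model of blood RNA and bounds favouring a mixture, their miR-16-5p needed 108% and 94.3% dried blood. miR-144-3p allowed 4.91% and 0.444%, so that for miR-144-3p allowed minus needed was -93.9 percentage points at the most. miR-451a allowed more, 6.24% and 8.35%, which also stayed below the need. In plasma 9 miR-16-5p lay above the highest dried blood library (489110 CPM before TMM scaling). No share of dried blood could meet that need, so for plasma 9 the outcome was fixed in advance. A swap with dried blood does not explain the 2 libraries, since miR-122-5p in the lower of them stood 54.6-fold above the highest dried blood library. Their source stays open, and no biological explanation was tested.

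Rare miRNAs clustered around one count per library. In the 19 libraries with a commonest count of 12 or more, the miRNAs with more than 2 reads but far below that count were at most 0.164 times as many as those near it. That window was centred on the count found in the same libraries, and the library used for a thinned comparison had the lowest commonest count, so neither decides whether copies of single molecules were counted without collapsing molecular identifiers. A minimum count set by the authors is argued against by counts of 1 or 2, held by at least 8 miRNAs in every library. The cause stays open, and no biological explanation was tested.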

How the results depend on the processing

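Of 102 alternative values for the comparisons, 87 kept their direction, call or size. With no filter on low counts (1199 miRNAs tested) 352 rose, 307 fell, 609 passed 2-fold and 13 lists were called. With library totals alone 49 rose and 146 of all 178 calls were kept (155 of 177 with the GC correction), and on counts divided by the commonest low count, chosen after seeing the data, 50 rose, 58 fell, 80 passed 2-fold and 3 lists were called, among the 136 miRNAs left. The stricter filter called 3 lists and an estimated correlation 0. Leaving out each sample number gave 71 to 82 rises, 94 to 102 falls, 118 to 135 past 2-fold and 5 to 8 lists; of the 46 called among the 54 named miRNAs, 6 lost a call somewhere and miR-142-3p turned to -0.30 with totals alone. miRNAs detected differed by -57.9 at 100 reads (permutation p = 0.00705) and -71.5 after thinning (p = 0.0133), in place of 1.6. The distance to the group mean differed by 0.25 among miRNAs with at least 100 CPM (permutation p = 0.0608, approximate since distances within a kind depend on each other), in place of -0.21. Same-numbered samples did not deviate together (mean rho 0.012, one-sided permutation p = 0.517, with 0.012 for other numbers, and -0.024 among abundant miRNAs), and 1 of 10 plasma libraries was nearest to its own number. With the replicate block 80 rose, 91 fell, 133 passed 2-fold and 6 lists were called. let-7i-5p (-0.46) and miR-128-3p (-0.66) turned with totals alone, and miR-128-3p (-0.041) with the stricter filter. miR-205-5p, near 0, turned to -0.012 with DESeq2 size factors and with DESeq2, -0.85 with totals alone, -0.13 with the stricter filter and -0.076 with summed names. It ranged from -0.41 to 1.00 over the fits leaving out a number, 5 of them below 0, and turned to -0.31 without plasma 9 and 10, -0.39 without dried blood 5 and 7, and -0.20 on divided counts. miR-29c-3p turned to 0.30 with the GC correction. The direction given by camera for the fragment list turned with the stricter filter (adjusted p = 0.881), although the median stayed above 0 (0.49). It also turned on divided counts (median -4.99). The cause of these changes was not tested.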

Other observations

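If equal sample numbers marked the same patient, levels in dried blood could be set against plasma for each miRNA. Over 78 miRNAs with at least 100 CPM in both kinds, 0 passed an adjusted p of 0.05 by Spearman or by Pearson permutation tests, 6 had an unadjusted p under 0.05 by each, and the median rho was -0.23, with 13 of 78 above 0. With library totals alone the median was -0.03 and 35 of 78 lay above 0, so the negative median depended on the scaling. The smallest adjusted p was 0.389 by Spearman and 0.263 by Pearson. miR-484 had a rho of -0.79 (permutation p = 0.00862, adjusted 0.389) and a Pearson r of -0.76 (permutation p = 0.0101), which went to -0.41 without the 2 plasma values farthest from the median. miR-30d-5p had a rho of -0.77 (permutation p = 0.0129, adjusted 0.389) and a Pearson r of -0.76 (p = 0.0037), and r was -0.75 without those 2. For miR-151a-3p, miR-185-5p, miR-425-3p and miR-625-5p rho was -0.75, -0.73, -0.70 and -0.65, with adjusted p from 0.389 to 0.638. These values hold for patients only if the numbers pair the samples, which the labels do not state and the profiles do not show.

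Splits of the 20 libraries into 10 and 10 show which counts chance can give. Of 100 splits, the real one included, 1 gave as many as 178 differing miRNAs and the highest other gave 2. For changes past 2-fold, 1 of 100 gave as many as 135 and the highest other gave 0, so chance is unlikely to give either count. With the real split counted, 1 of 100 is the smallest share possible. The other splits mix the 2 kinds in varying proportions, so part of the difference between the kinds can remain in them or widen their spread. For the 7 shifted lists chance cannot be excluded, since 7 of 100 splits gave as many and the highest other gave 9.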
